A study of Mus musculus with 26 samples.

How the data were processed

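Gene expression was measured on 26 Affymetrix Mouse Gene arrays in murine Ba/F3/gp130 cells, an interleukin-3 or Hyper-IL-6 dependent pro-B cell line, carrying natural or synthetic IL-22 receptors. Per the labels' protocols, cells were washed 4 times and starved for 4 h without serum. Purified protein followed at 100 ng/ml for 2 h, as no label indicates another time. Per the same protocols, 150 ng of total RNA with an RNA integrity number above 8 was amplified and labelled.

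The deposited values are log2 intensities per probe set that the authors made with Affymetrix Expression Console 4.0 at the core gene or exon level, per the labels' description. The labels do not state the authors' algorithm, background correction or any filter. The log2 scale was checked on the deposited values, which spanned 1.79 to 14.31, with array medians of 6.06 to 6.28. No pair of arrays held identical values, and all 26 columns were mapped to samples.

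Of 35556 probe sets, 21789 were paired with 1 gene symbol in the annotation supplied with the series, 1621 with several and 12146 with none. Entrez identifiers matched current gene records for 21698 of the 21789, and the other 91 kept the annotation's name. Probe sets with several symbols were left out, and those with none were tested apart from the genes. For 999 genes with several probe sets the one with the highest mean over all 26 arrays was used, leaving 19938 genes. No filter on dim genes was applied. The files give no genome build, so no coordinates are reported.

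All 26 arrays in 5 groups entered one linear model per gene (R 4.3.3, limma 3.58.1, lmFit and eBayes), so that all groups shared one estimate of the spread. Contrasts were tested with limma's moderated test, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 19938 genes with a threshold of 0.05. Intervals are 95% intervals of the model. The 6 comparisons were IL-22 against untreated cells with natural receptors, GFP-mCherry against untreated, mCherry-Fc against untreated and GFP-mCherry against mCherry-Fc in cells with synthetic receptors, the GFP-mCherry response minus the IL-22 response, and untreated synthetic against untreated natural receptor cells. In the text, rose and fell describe genes past the threshold. Counts adjusted over a list alone use the same p-values adjusted within that list.

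26 gene lists holding 554 genes, 483 of them measured, were written from general knowledge of the pathways before the data were examined, as were the comparisons, the model, the rule for named genes and the alternatives other than those by replicate number range. Those reported cover STAT3 feedback and target genes, STAT5 targets, the SOCS family, immediate early and MAPK feedback genes, FOXO and starvation genes, MYC and ribosome biogenesis, G1/S and G2/M cell cycle genes, cholesterol synthesis, glycolysis and hypoxia, amino acid and endoplasmic reticulum stress, the BCL2 family, NF-kB targets, epithelial IL-22 targets, the IL-10 response, cytokine receptors with JAK-STAT genes, markers of B lineage, T, myeloid, mast and erythroid cells, heat shock genes, replication-dependent histones, cytosolic ribosomal proteins and oxidative phosphorylation. Lists were tested with limma's camera at a preset correlation of 0.01, which asks whether a list's genes rank higher or lower than the other genes, with Benjamini-Hochberg adjustment over the 26 lists within each comparison. Results of 1 list are left out of the text. Each list test was repeated with a correlation estimated from the data, and with limma's fry.

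Genes named in the text follow a rule. In each comparison they are the 8 largest rises and 8 largest falls past the threshold, the 3 called members with the smallest p of each list past camera's threshold, and in every comparison Socs3, Cish, Socs1, Socs2, Pim1, Bcl3, Junb, Stat3, Myc, Egr1, Il10rb, Il22ra1 and Il6st. Predicted loci, small RNA genes and immunoglobulin or T cell receptor segments were left out. Other list members named to spell out a small count, and genes said to be outside the rule, were chosen after their values were seen.

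Alternatives were quantile normalization again, centring of each array on its median, the mean of all probe sets of a gene, a lenient and a stricter filter on genes with a low mean, a trended and robust variance prior, array weights, a fit with only the groups compared, a minimum change of 1.5-fold, the replicate number as a fixed or random block, and leaving out each array in turn. Principal components of the data separated low replicate numbers (natural 1 to 3, synthetic 7 to 11) from high ones (natural 4 and 5, synthetic 12 to 15), except among GFP-mCherry arrays. These overlapped on each of the first 4 components, so their split rests on the other groups. Each result was also computed within each range. Except between the untreated lines, whose ranges share no number, it was also computed with the low and high split as a batch term in each line. Those alternatives were chosen after seeing the data.

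Replicate numbers come from the sample titles, which do not say what a number marks. Deviations from the group means of same-numbered arrays correlated at 0.313 to 0.621 over 3 pairs of IL-22 and untreated arrays, 0.260 to 0.466 over 3 pairs of mCherry-Fc and untreated arrays, and 0.105 to 0.271 over 3 pairs of GFP-mCherry and mCherry-Fc arrays. Over 6 pairs of GFP-mCherry and untreated arrays the range was -0.146 to 0.417. Arrays of different numbers from one range correlated about as much in 2 comparisons with untreated. Medians were 0.334 for IL-22 and 0.319 for mCherry-Fc, beside 0.378 and 0.326 for the same number.

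The scripts were tested on simulated data with 200 of 19938 genes changed. Of genes changed 1.5-fold, the test recovered 93% with IL-22, 97% with GFP-mCherry and 98% with mCherry-Fc against untreated. It recovered 99% between the ligands, 74% for the difference of responses and 91% between the untreated lines. False calls made up 5.39% to 7.51% of the calls. With no change 0 lists were called, and a list shifted by 0.3 was called. Simulated genes varied independently, so correlation within a list is not covered. The labels do not say whether replicates are separate cultures, so p-values describe only the spread between these arrays, and the number of arrays limits the precision of every value.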

Results

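The arrays measured RNA in Ba/F3/gp130 cells, murine pro-B cells that also carry gp130, the signal chain shared by cytokines of the IL-6 family. Natural receptor cells expressed IL-10R2 and IL-22Rα1, the receptor pair of IL-22, and were untreated (n = 4) or given IL-22 (n = 4). Synthetic receptor cells expressed the same chains with nanobodies outside the cell, an mCherry nanobody on IL-10R2 and a GFP nanobody on IL-22Rα1, and were untreated (n = 6), given a GFP-mCherry fusion that can bind both chains (n = 6), or given dimeric mCherry-Fc (n = 6), which has only the mCherry nanobody chain to bind. No group got a control protein, so contrasts with untreated cells do not separate joining of chains from adding protein. Within groups, arrays correlated at 0.981 to 0.994 across probe sets. The first principal component held 41.2% of the variance.

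The chains themselves were read first. Il22ra1 (probe set 10509063) stood at 12.31 ± 0.11 (log2 intensity, mean ± SD, n = 4) in untreated natural receptor cells and at 6.32 ± 0.10 (n = 6) in untreated synthetic receptor cells. That was 63.9-fold lower (log2 -6.00, SE 0.06, limma's Benjamini-Hochberg adjusted p = 6.79e-32), with all 6 synthetic arrays below all 4 natural ones. A second, dimmer Il22ra1 probe set, 10509071, did not differ between the lines by the test (log2 0.16, adjusted p = 0.369), so the difference was seen by 1 of 2 probe sets. Il10rb, which encodes IL-10R2 and has a mouse copy of its own, stood at 11.95 ± 0.23 against 10.05 ± 0.07 and was 3.71-fold lower (log2 -1.89, SE 0.08, adjusted p = 3.39e-16), again in 6 of 6 arrays. The labels do not say which parts of the constructs, or of which species, the probes match, so these values do not compare receptor levels at the cell surface. The Il6st probe set, for gp130, was near the dim end of the array in all groups, with group means of 4.86 to 5.05, and passed no test.

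**Figure D1:**
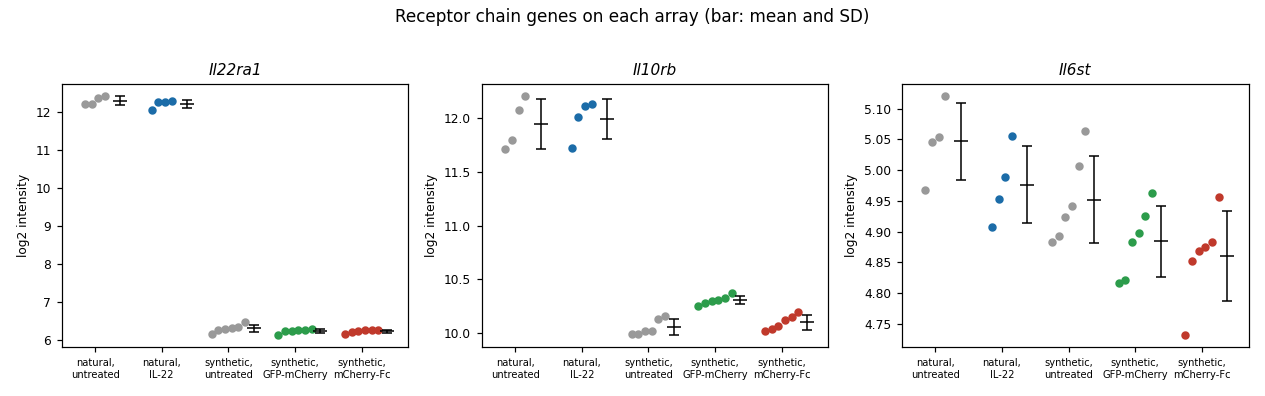
Log2 intensity of the Il22ra1, Il10rb and Il6st probe sets on each array (points, in order of value) with group means and SD (bars), for the 5 groups. Il22ra1 was 12.31 in untreated natural and 6.32 in untreated synthetic receptor cells, and Il6st had group means between 4.86 and 5.05.

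IL-22 against untreated cells asked what this ligand changes. Socs3 (probe set 10393449), which encodes a feedback inhibitor of gp130 and JAK signals, rose 19.7-fold, from 7.53 ± 0.20 to 11.83 ± 0.06 (log2 4.30, SE 0.09, n = 4 against 4, limma's adjusted p = 7.24e-24), and a second Socs3 probe set, 10383010, rose by 3.25. Il2ra, the IL-2 receptor alpha chain and a STAT5 target, rose 15.7-fold (log2 3.98, SE 0.15, adjusted p = 2.42e-17). Il4ra rose 14.9-fold (log2 3.89, SE 0.08, adjusted p = 1.53e-23), and Gadd45g, a growth arrest gene, 12.7-fold (log2 3.66, SE 0.11, adjusted p = 1.79e-19). Zfp36, whose product destabilises cytokine mRNAs, rose 10.2-fold, and the cytokine genes Il6 and Osm rose 9.47-fold and 8.17-fold. Tgm1, a transglutaminase, rose 7.47-fold. Among the always named genes Cish rose by 2.06 (4.17-fold), Junb by 1.69, Pim1 by 1.67 (3.18-fold), Stat3 by 0.98, Bcl3 by 0.96, Socs2 by 0.61, Myc by 0.57 and Socs1 by 0.42. Egr1 did not pass (log2 -0.09, adjusted p = 0.796), nor did Il10rb, Il22ra1 or Il6st.

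The largest fall was in Mc5r, a melanocortin receptor, at 4.87-fold (log2 -2.28, SE 0.15, adjusted p = 2.3e-12). Ccng2, a cyclin G gene that FOXO factors raise in resting cells, fell 3.93-fold (log2 -1.97, SE 0.33, or -2.59 without IL-22 replicate 5 and -0.57 within high replicate numbers), and Cdkn1b, which encodes the cell cycle inhibitor p27, fell 2.44-fold (log2 -1.29, SE 0.16). Gfi1b, a transcriptional repressor that acts in the erythroid and megakaryocyte lineages, fell 2.80-fold (log2 -1.49, SE 0.09, limma's adjusted p = 5.06e-13). Klf1, an erythroid transcription factor, fell 2.18-fold (log2 -1.12, SE 0.07). Arrdc3 and Sh2d3c each fell by 1.49, Cnr2, a cannabinoid receptor, by 1.36, and Cdc42ep3 by 1.34. Of 54 called named genes, all 54 had all 4 IL-22 arrays on the called side of the untreated mean, and 50 had no overlap between the groups, as genes picked for passing largely must.

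Of 26 STAT3 feedback and target genes 22 rose (median 1.33, camera's adjusted p = 1.32e-50), including Sbno2, a corepressor of the IL-10 response that rose 7.01-fold. STAT5 targets rose in 11 of 20 (median 0.55, adjusted p = 4.99e-17), the IL-10 response in 11 of 17 (median 0.75, adjusted p = 1.53e-23) and the SOCS family in 6 of 8 (median 0.38, adjusted p = 1.81e-12). Immediate early and MAPK feedback genes rose in 16 of 30 (median 0.59, adjusted p = 8.43e-15), with Egr2 up by 2.10, Lif by 1.98 and Spry2 by 1.12, while Dusp4, Dusp6 and Klf6 fell. NF-kB targets rose in 10 of 22 (median 0.13, adjusted p = 1.88e-06), among them Tnip3 by 1.99 and Icam1 by 1.04, while Tnfaip3 and Tnip1 fell. Cytokine receptor and JAK-STAT genes rose in 7 of 25 (median 0.05, adjusted p = 2.19e-06), Stat5a by 1.53, and Ifngr1 fell. Heat shock genes rose in 3 of 12, Dnajb1, Ahsa1 and Dnaja1 (median 0.08, adjusted p = 0.000543), and Dnajb1 by 1.24. These 8 lists also passed with an estimated correlation.

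FOXO and starvation genes fell in 10 of 25 (median -0.11, adjusted p = 0.00168), with Sesn1 at -1.01 and Bcl6 the 1 that rose (log2 1.49), and this too held with an estimated correlation. G2/M genes fell in 7 of 19 (median -0.18, adjusted p = 9.2e-05), with Kif20a at -0.44 and Plk1 at -0.31, but the adjusted p was 0.184 with an estimated correlation. G1/S genes fell in 10 of 28 (median -0.10, adjusted p = 0.00563, adjusted p = 0.303 with an estimated correlation), with Cdt1 at -0.60, Slbp at -0.47 and Cdc25a the 1 that rose. MYC and ribosome biogenesis genes rose in 17 of 34 (median 0.27, adjusted p = 2.13e-12, adjusted p = 0.116 with an estimated correlation), with Rrp12 up by 0.82 and Nop2 by 0.63, and Tfrc, the transferrin receptor, fell. Erythroid markers fell in 3 of 10, Klf1, Tfrc and Epor (median -0.06, adjusted p = 0.0271, adjusted p = 0.124 with an estimated correlation), and the call was lost without IL-22 replicate 2 (adjusted p = 0.0509). Amino acid and endoplasmic reticulum stress genes rose in 4 of 28, Mthfd2, Slc7a5, Nupr1 and Xbp1, and Dnajb9 fell (median 0.06, adjusted p = 0.0271, adjusted p = 0.162 with an estimated correlation). That call was lost without IL-22 replicate 2 (adjusted p = 0.0531) or 3 (0.0604), without untreated replicate 4 (0.0703) or 5 (0.0698), and with quantile normalization (0.0931). Among these genes, and with 1 of 2 Dnaja1 probe sets passing, Dnaja1 and Epor lost their calls without IL-22 replicates 1, 2 or 3 or untreated replicates 4 or 5 (adjusted p = 0.0521, 0.0796, 0.135, 0.0822 and 0.0647 for Dnaja1, and 0.157, 0.0573, 0.115, 0.0910 and 0.103 for Epor), and with the replicate block (0.0521 and 0.0960), as did Tfrc (0.0594).

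Lists that did not pass in this comparison were the BCL2 family (adjusted p = 0.313), in which Bcl2l1, Mcl1 and Bmf rose and Bcl2, Bcl2l11 and Bbc3 fell, and glycolysis and hypoxia (0.892), in which Hk2, Slc2a1 and Pfkfb3 rose, Ankrd37 and Bnip3l fell and the median (-0.08) and the mean differed in sign. Ribosomal proteins (0.892), oxidative phosphorylation (0.417), T cell markers (0.724) and B lineage markers (0.724), in which Cd79b fell, did not pass either. Mast cell markers (0.940), in which Gata2 fell, had a median above and a mean below 0. Epithelial IL-22 targets did not pass (0.0560) although Lbp, a plasma lipopolysaccharide binding protein, rose by 2.35 and Muc1 and Muc13 also rose. The list passed without IL-22 replicate 2 (0.0299), without untreated replicate 4 (0.0326) or 5 (0.0328) and with the replicate block (0.0283). Cholesterol synthesis (0.123), in which Srebf2 and Pmvk rose and Tm7sf2 fell, passed without IL-22 replicate 5 (0.00633) or untreated replicate 2 (0.0111) or 3 (0.0301). Myeloid markers (0.309), in which Fcgr1 and Prtn3 rose and whose median (0.04) and mean (-0.12) differed in sign, passed as raised without untreated replicate 5 (0.0196), and histones (0.138) as lowered without untreated replicate 4 (0.0408) or 5 (0.0479). Adjusted over the list alone, the counts past the threshold were 22 for STAT3 targets, 13 for STAT5 targets, 12 for the IL-10 response, 7 for the SOCS family, 20 for immediate early genes, 13 for NF-kB targets, and 10 for cytokine receptors. For growth and stress lists they were 22 for MYC, 12 for FOXO, 11 for G1/S, 8 for G2/M, 6 for amino acid stress, 6 for glycolysis, 7 for the BCL2 family, and 4 for epithelial IL-22 targets. They were 3 each for heat shock, cholesterol, erythroid and myeloid genes, and 1 each for B lineage and mast cell markers.

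With IL-22, 2277 of 19938 genes passed, 1075 higher and 1202 lower (47.2% higher, or 58.9% after median centring), and 196 changed at least 2-fold, 173 of them higher. Within low replicate numbers 3212 genes passed and within high ones 759, where a single IL-22 array was assumed to vary like the other groups, and with the number range as a batch term 3021 passed. Fitted with only its own groups 1222 passed, and Plk1, Cenpf, Dnaja1, Tfrc, Epor, Socs2 and the amino acid stress and erythroid lists lost their calls. Within high numbers so did Bcl6 (adjusted p = 0.146), Cdt1 (0.190), Slbp (0.120), Cdca7 (0.104), Plk1 (0.209), Cenpf (0.106), Ahsa1 (0.0855), Dnaja1 (0.710), Tfrc (0.350), Epor (0.785), Socs1 (0.347) and the amino acid stress (0.110), G1/S (0.370) and erythroid lists (0.182). Amino acid stress also failed within low ones (0.0598).

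GFP-mCherry against untreated cells asked what this ligand changes. Nfkbia (probe set 10400405), which encodes the NF-kB inhibitor IκBα, rose 9.37-fold, from 8.51 ± 0.15 to 11.73 ± 0.14 (log2 3.23, SE 0.17, n = 6 against 6, limma's adjusted p = 1.57e-13). Nfkbie rose 5.27-fold (log2 2.40, SE 0.08, adjusted p = 2.11e-18), Nfkbiz by 2.33 and Zc3h12a, an RNase that limits cytokine mRNAs, by 2.20. Gpr84, a receptor for medium-chain fatty acids, rose 5.67-fold (log2 2.50, SE 0.11). Pim1 and Pim2, survival kinases downstream of STATs, rose 5.24-fold (log2 2.39, SE 0.15, adjusted p = 4.7e-12) and 5.01-fold (log2 2.33, SE 0.17), and Ier3 4.46-fold (log2 2.16, SE 0.26). Cish rose by 1.06, Socs3 by 1.02 (2.03-fold, SE 0.07, adjusted p = 2.46e-11), Myc by 0.97, Junb by 0.75, Socs2 by 0.61, Bcl3 by 0.35 and Il10rb by 0.25 (adjusted p = 0.0106, failing after quantile normalization). Socs1 (log2 -0.02), Stat3 (-0.05), Egr1 (0.09), Il22ra1 and Il6st did not pass. The second Socs3 probe set did not pass (log2 0.20, adjusted p = 0.155), and the second Il22ra1 probe set passed as lower (log2 -0.26, adjusted p = 0.0397).

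Falls were smaller. Cd180, a Toll-like receptor homologue of B cells, fell (log2 -1.21, SE 0.24, adjusted p = 0.000528), and Ly96, the MD-2 partner of TLR4, was at -0.73 (SE 0.11, adjusted p = 2.9e-05). Olfr248 (log2 -1.08), Bex6 (-0.89), Olfr417 (-0.87), Proser3 (-0.71), Sh2d3c (-0.67) and Crebrf (-0.65) completed the 8 largest falls. Of 56 called named genes, all 56 had all 6 GFP-mCherry arrays on the called side of the untreated mean, and 54 had no overlap between the groups.

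NF-kB targets rose in 15 of 22 with GFP-mCherry (median 0.83, camera's adjusted p = 3.04e-16), Icam1 by 1.45, Tnip3 by 1.14 and Nfkb2 by 1.13, and 1, Rel, fell. MYC and ribosome biogenesis genes rose in 28 of 34 (median 0.36, adjusted p = 1.94e-20), Nop56 by 0.83 and Nop2 by 0.74. Oxidative phosphorylation genes rose in 15 of 20 (median 0.26, adjusted p = 5.07e-12), Cox5a by 0.72 and Cox5b by 0.49. Immediate early and MAPK feedback genes rose in 17 of 30 (median 0.43, adjusted p = 1.12e-10), Dusp4 by 1.26 and Spred2 by 0.91, and Klf6 fell. STAT3 targets rose in 17 of 26 (median 0.37, adjusted p = 1.12e-10), Il4ra by 1.13, STAT5 targets in 12 of 20 (median 0.33, adjusted p = 1.59e-07) with Lrrc32 lower. The SOCS family rose in 5 of 8, Socs3, Cish, Socs2, Socs6 and Socs7 (median 0.25, adjusted p = 3.81e-05). The IL-10 response rose in 8 of 17 (median 0.06, adjusted p = 0.0017), and Cd163 fell. These 8 lists also passed with an estimated correlation.

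Ribosomal protein genes rose in 15 of 21 (median 0.18, adjusted p = 3.9e-07, adjusted p = 0.133 with an estimated correlation), Rplp1 by 0.52 and Rpl8 by 0.40. Histone genes rose in 4 of 10, H2ac4, H1f5, H2bc3 and H1f3 (median 0.20, adjusted p = 0.00549, adjusted p = 0.318 with an estimated correlation), H2ac4 by 0.97, and H2bc3 lost its call without GFP-mCherry replicate 12 (adjusted p = 0.0586). G2/M genes fell in 9 of 19 (median -0.15, adjusted p = 0.00318, adjusted p = 0.349 with an estimated correlation), Cenpe at -0.45 and Mki67 at -0.44, and Ube2c rose. FOXO genes fell in 10 of 25 (median -0.13, adjusted p = 0.01, adjusted p = 0.0625 with an estimated correlation), Klf6 at -0.64, Tsc22d3 at -0.45 and Gadd45a at -0.40, and Sesn1 rose. Amino acid and endoplasmic reticulum stress genes rose in 9 of 28 (median 0.11, adjusted p = 0.00661, adjusted p = 0.0839 with an estimated correlation), Slc7a5 by 0.58, while Ddit3, Vldlr and Dnajb9 fell. Heat shock genes rose in 5 of 12, Hspe1, Ahsa1, Hspd1, Hsph1 and Dnajb1 (median 0.07, adjusted p = 0.0108, adjusted p = 0.0786 with an estimated correlation). G1/S genes rose in 8 of 28 (median 0.06, adjusted p = 0.0147, adjusted p = 0.394 with an estimated correlation), Ccnd2 by 0.37 and Cdk4 by 0.33, while Gins2 and Cdk2 fell, and quantile normalization ended that call (adjusted p = 0.686). Within low replicate numbers the calls of histones (0.462) and H2bc3 (0.440) were also lost, and within high ones those of G1/S (0.0899) and Hspd1 (0.0978).

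Cytokine receptors did not pass with GFP-mCherry (adjusted p = 0.634), with Il4ra, Ifngr2 and Il10rb higher, Csf2rb2 and Stat2 lower and a median (-0.05) below and a mean above 0. Epithelial IL-22 targets (0.697) held Hp and Muc1 as rises and Reg3b, Muc13, Defb1 and Dmbt1 as falls. The BCL2 family (0.178) held Bcl2l1, Mcl1 and Bid as rises and Bik and Bok as falls. Cholesterol synthesis (0.172), with 7 genes lower and Mvd, Pmvk and Ebp higher, passed as lowered after quantile normalization and without untreated replicate 7 (0.0279). Glycolysis and hypoxia (0.145), with Hk2, Pfkfb3, Pgam1 and Car9 higher, passed as raised without untreated replicate 11 (0.0425). Markers of B lineage (0.488, Cd79a higher, Vpreb2 and Vpreb3 lower), T cells (0.212, Cd247 and Zap70 lower), mast cells (0.338, Mcpt2 and Mcpt8 lower), myeloid cells (0.742, Prtn3 and Spi1 higher) and erythroid cells (0.840, Epor and Tfrc higher, Klf1 lower) did not pass. Adjusted over the list alone, 18 NF-kB, 31 MYC, 18 oxidative phosphorylation, 18 immediate early, 18 STAT3, 13 STAT5, 5 SOCS, 10 IL-10, 19 ribosomal, 4 histone, 11 G2/M, 13 FOXO, 13 amino acid stress, 5 heat shock, 10 G1/S, 5 cytokine receptor, 7 epithelial IL-22, 6 BCL2, 12 cholesterol, 4 glycolysis, 3 erythroid, 2 myeloid, 2 mast cell and 1 B lineage genes passed.

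With GFP-mCherry 5183 genes passed, 2839 higher and 2344 lower (54.8% higher), 224 of them changed at least 1.5-fold and 42 at least 2-fold. The split depended on the scaling, with 82.5% higher after median centring and 70.4% without the dimmer genes, and 5985 genes passed within low replicate numbers, 4054 within high ones and 6947 with the batch term.

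**Figure D2:**
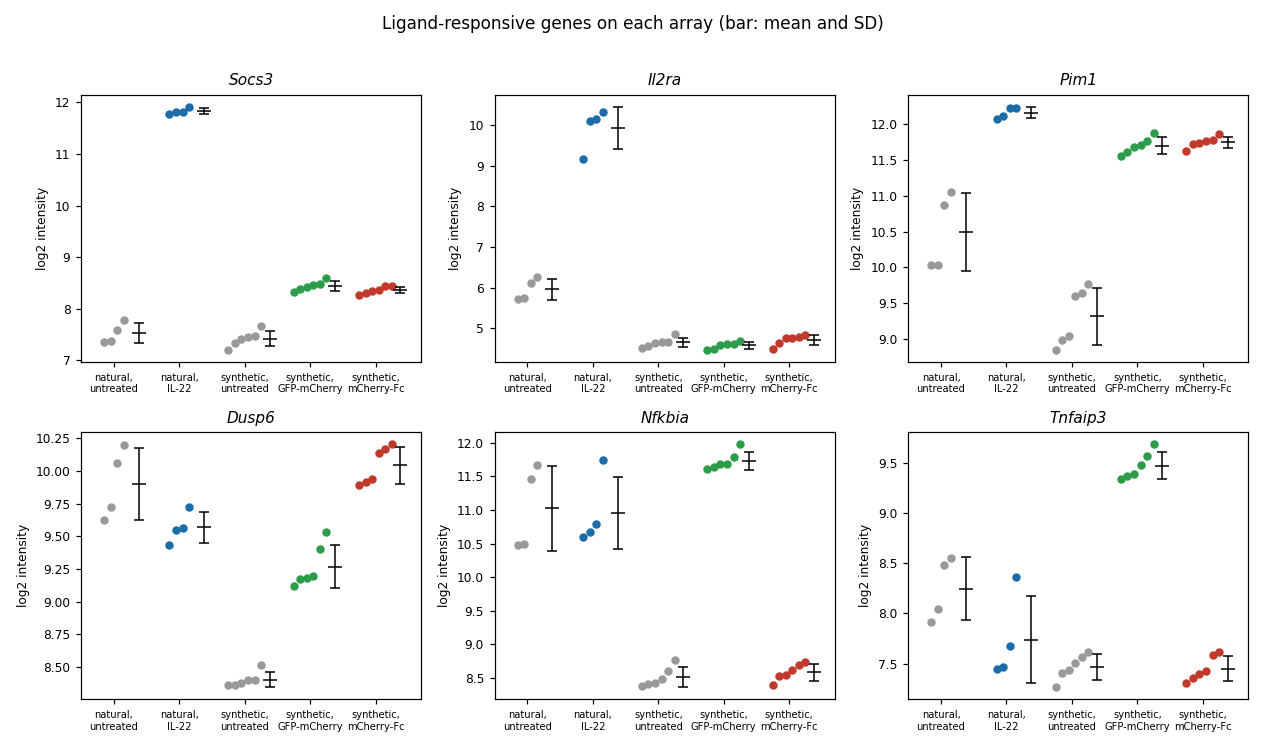
Log2 intensity of Socs3, Il2ra, Pim1, Dusp6, Nfkbia and Tnfaip3 on each array (points, in order of value) with group means and SD (bars), for the 5 groups. Socs3 reached 11.83 with IL-22 and 8.45 with GFP-mCherry, and Nfkbia reached 11.73 with GFP-mCherry and 8.58 with mCherry-Fc.

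mCherry-Fc against untreated cells asked what this ligand changes. Pim1 (probe set 10443527) rose 5.41-fold, from 9.31 ± 0.40 to 11.75 ± 0.08 (log2 2.44, SE 0.15, n = 6 against 6, limma's adjusted p = 8.24e-12), and Pim2 3.59-fold (log2 1.84, SE 0.17). Id1, an inhibitor of differentiation, rose 3.32-fold (log2 1.73, SE 0.10, adjusted p = 2.41e-12). The ERK phosphatase genes Dusp6 and Dusp4 rose 3.11-fold (log2 1.64, SE 0.09, adjusted p = 4.04e-13) and 2.99-fold (log2 1.58, SE 0.09). The ERK-responsive transcription factor genes Etv5, Myc and Fosl1 rose 2.84-fold, 2.63-fold (log2 1.40, SE 0.07, adjusted p = 2.78e-13) and 2.41-fold. Socs3 rose by 0.94 (1.92-fold, SE 0.07, adjusted p = 3.45e-10), Socs2 by 0.53, Junb by 0.47 and Cish by 0.43. Junb lost its call with the replicate block (adjusted p = 0.0629), and the second Socs3 probe set did not pass (log2 0.16, adjusted p = 0.240). Bcl3 (log2 0.11), Stat3 (0.09), Socs1 (-0.11), Egr1 (-0.05), Il10rb (0.05), Il22ra1 and Il6st did not pass. Falls were small, and dimmer genes, where lower background is not excluded, held 1685 of 2583 lower calls but 80 higher ones. The largest was in Krtap5-3 (1.58-fold, log2 -0.66, SE 0.11, adjusted p = 5.87e-05). Olfr316 (-0.63), Otx1 (-0.62), Krtap5-2 (-0.62), Tns1 (-0.59), Olfr419 (-0.57), Pmch (-0.57) and Usp46os2 (-0.54) followed, but 5 other Tns1 probe sets did not pass. Of 52 called named genes, all 52 had all 6 mCherry-Fc arrays on the called side of the untreated mean, and 47 had no overlap between the groups.

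MYC and ribosome biogenesis genes rose in 29 of 34 with mCherry-Fc (median 0.35, camera's adjusted p = 8.08e-23), Nop56 by 0.87 and Nop2 by 0.79. Immediate early and MAPK feedback genes rose in 19 of 30 (adjusted p = 3.62e-11), and Klf6 fell. Oxidative phosphorylation genes rose in 15 of 20 (median 0.24, adjusted p = 2.93e-10), Cox5a by 0.67, Cox5b by 0.47 and Sdhb by 0.35. STAT3 targets rose in 16 of 26 (median 0.28, adjusted p = 2.14e-08) with Timp1 lower, STAT5 targets in 11 of 20 (median 0.37, adjusted p = 1.89e-07), Bcl2l1 by 0.70, with Gfi1 lower. SOCS family genes rose in 5 of 8, Socs3, Socs2, Cish, Socs4 and Socs6, the last by 1 of its 3 probe sets (median 0.32, adjusted p = 0.000154). These 6 lists also passed with an estimated correlation. Ribosomal protein genes rose in 11 of 21 (median 0.14, adjusted p = 1.01e-05, adjusted p = 0.222 with an estimated correlation), Rplp1 by 0.42 and Rpl8 by 0.37, and Rpl10a fell. G1/S genes rose in 9 of 28 (median 0.09, adjusted p = 0.00147, adjusted p = 0.263 with an estimated correlation), Ccnd2 by 0.43, with Gins2 lower, and quantile normalization ended this call (0.309). Amino acid and endoplasmic reticulum stress genes rose in 10 of 28 (median 0.12, adjusted p = 0.00422, adjusted p = 0.0853 with an estimated correlation), Creld2 by 0.43. Heat shock genes rose in 6 of 12 with Hspb1 lower (median 0.17, adjusted p = 0.00422, adjusted p = 0.0520 with an estimated correlation), Ahsa1 by 0.33.

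The IL-10 response passed as raised with mCherry-Fc (adjusted p = 0.0318, adjusted p = 0.188 with an estimated correlation) with a median of -0.02 and a mean of 0.16, Sbno2 at 0.47, 6 genes higher and Il21r and Maf lower, and failed without untreated replicate 13 (0.0685) or 14 (0.0566) or mCherry-Fc replicate 9 (0.0527) and after centring (0.0635). FOXO genes fell in 4 of 25, Klf6, Gadd45a, Tsc22d3 and Pik3ip1 (median -0.14, adjusted p = 0.0363, adjusted p = 0.149 with an estimated correlation), and failed without untreated replicate 13 (0.0685) or mCherry-Fc replicate 8 (0.0538). Cholesterol synthesis rose in 4 of 20, Mvd, Ebp, Pmvk and Sqle (median 0.11, adjusted p = 0.0318, failing with an estimated correlation). It failed after quantile normalization (0.519) or centring (0.0625), and without untreated replicate 7 (0.119), 9 (0.0557) or 11 (0.0709) or mCherry-Fc replicate 13 (0.0869), 14 (0.0788) or 15 (0.0629). Pmvk itself failed without untreated replicate 7 (0.0558) or 11 (0.0512) or mCherry-Fc replicate 13 (0.0817) or 14 (0.0648) and with the replicate block (0.0751). Glycolysis and hypoxia genes rose in 5 of 23, Hk2, Pgam1, Pfkfb3, Pfkl and Tpi1, with Egln3 lower (median 0.08, adjusted p = 0.0318, adjusted p = 0.560 with an estimated correlation). It failed after quantile normalization (0.116) and without untreated replicate 13 (0.0929) or 14 (0.0940) or mCherry-Fc replicate 8 (0.0613), 9 (0.0633) or 10 (0.0734), and Pfkfb3 failed with the replicate block (0.0669). Histones rose in 2 of 10, H2ac4 and H1f5 (median 0.09, adjusted p = 0.0480, adjusted p = 0.486 with an estimated correlation). They failed with the replicate block (0.0632), after quantile normalization (0.109), and without untreated replicate 12 (0.0598), 13 (0.179) or 14 (0.0960) or mCherry-Fc replicate 8 (0.0613), 9 (0.0633) or 10 (0.104).

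NF-kB targets did not pass with mCherry-Fc (median 0.06, adjusted p = 0.249), with 6 of 22 higher and Rel lower. G2/M genes (0.529) held Aurka, Aurkb and Ube2c as rises and Mki67 as a fall. The BCL2 family (0.362) held Bcl2l1 and Bid as rises and Bik and Bok as falls, and cytokine receptors (0.992) Il4ra and Ifngr2 as rises and Il6ra and Il21r as falls. Epithelial IL-22 targets (0.0897), with Hp higher and Reg3b, Muc13, Orm1 and Dmbt1 lower, passed as lowered with the replicate block (0.0327). T cell markers (0.0897), with Cd3e, Cd247, Cd4, Zap70 and Cd5 lower, passed as lowered without untreated replicate 13 (0.0468) or mCherry-Fc replicate 10 (0.0490). Markers of B lineage (0.281, Vpreb2 and Vpreb3 lower), mast cells (0.198, Mcpt2, Mcpt8, Tpsb2 and Tpsab1 lower), myeloid cells (0.992, Prtn3 higher, Csf3r lower) and erythroid cells (0.752, Epor and Tfrc higher, Klf1 lower) did not pass. Adjusted over the list alone, 31 MYC, 20 immediate early, 17 oxidative phosphorylation, 17 STAT3, 14 STAT5, 6 SOCS, 14 ribosomal, 10 G1/S, 12 amino acid stress, 8 heat shock, 10 IL-10, 4 FOXO, 3 cholesterol, 6 glycolysis, 2 histone, 7 NF-kB, 4 G2/M, 1 epithelial IL-22, 5 BCL2, 4 cytokine receptor, 5 T cell, 4 mast cell, 3 erythroid, 2 B lineage and 1 myeloid genes passed.

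With mCherry-Fc 5371 genes passed, 2788 higher and 2583 lower (51.9% higher), 133 of them changed at least 1.5-fold and 12 at least 2-fold, and quantile normalization gave 3146. The share of higher calls was 85.5% after median centring and 73.8% without the dimmer genes, and 4910 genes passed within low replicate numbers, 4041 within high ones and 7392 with the batch term. Within low numbers Olfr316 (adjusted p = 0.0538), Mvd (0.195), Pmvk (0.118), Rpl19 (0.129), FOXO genes (0.0871), the IL-10 response (0.0806) and histones (0.259) lost their calls, and within high ones Tsc22d3 (0.0859), heat shock genes (0.0721) and the IL-10 response (0.0836). Quantile normalization ended those of Ebp, Pmvk and Pfkfb3.

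GFP-mCherry against mCherry-Fc asked how joining IL-10R2 with IL-22Rα1 differs from joining IL-10R2 chains to each other, with the ligand protein changed as well. Nfkbia was 8.90-fold higher with GFP-mCherry (log2 3.15, SE 0.17, n = 6 against 6, limma's adjusted p = 5.11e-13), and Tnfaip3, which encodes the ubiquitin-editing NF-kB inhibitor A20, was 4.08-fold higher (log2 2.03, SE 0.12, adjusted p = 3.19e-12). Gpr84, Nfkbiz, Zc3h12a and Nfkbie were higher by 2.04, 2.03, 1.90 and 1.89, Tnf 2.73-fold (log2 1.45, SE 0.17, adjusted p = 3.39e-06) and the sugar transporter gene Slc2a6 by 1.39. Lower with GFP-mCherry were Bex6 (log2 -1.09, SE 0.13), Id1 (-0.92, SE 0.10, adjusted p = 8.88e-07), Dusp6 (-0.78, SE 0.09, adjusted p = 1.13e-06), Olfr417 (-0.74), Insig1 (-0.71), Sla (-0.70), Egr2 (-0.67) and Hhex (-0.54). Myc was also lower (log2 -0.42, SE 0.07, adjusted p = 0.000636) and Cish higher (log2 0.63). Socs3 did not differ by the test (log2 0.08, 95% interval -0.06 to 0.23, adjusted p = 0.824), nor did Pim1 (log2 -0.05), Socs2 (0.08), Stat3 (-0.14), Socs1, Bcl3, Junb, Egr1, Il10rb, Il22ra1 or Il6st. Of 28 called named genes all 28 separated the groups without overlap. With the replicate block, which rests on 3 shared numbers, Cish (adjusted p = 0.0747), Egr2 (0.281), Hhex (0.0540), Olfr417 (0.0578), Il4ra (0.375), Ier3 (0.120), Fdft1 (0.135), Hmgcs1 (0.225) and Tpx2 (0.237) lost their calls.

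NF-kB targets were higher with GFP-mCherry in 13 of 22 (median 0.95, camera's adjusted p = 8.35e-54), with Icam1 higher by 1.21 and Tnip3 by 0.99, and the list also passed with an estimated correlation (adjusted p = 3.5e-08). Cholesterol synthesis genes were lower in 6 of 20 (median -0.20, adjusted p = 9.6e-12, adjusted p = 0.239 with an estimated correlation), Msmo1 at -0.52 and Fdft1 at -0.33. In the G2/M list 1 of 19, Tpx2, was lower, and the list passed (median -0.15, adjusted p = 2.53e-14, adjusted p = 0.0506 with an estimated correlation). Tpx2 lost its call without GFP-mCherry replicate 7 (0.0794), 9 (0.0835), 11 (0.0521) or 12 (0.0630) or mCherry-Fc replicate 8 (0.0517), 13 (0.0786), 14 (0.0693) or 15 (0.0625). STAT3 targets were higher in 3 of 26, Icam1, Ier3 and Il4ra (median 0.03, adjusted p = 0.0105, adjusted p = 0.529 with an estimated correlation), and failed with the replicate block (0.267). The IL-10 response was higher in 2 of 17, Tnip3 and Il4ra (median 0.05, adjusted p = 0.0197, adjusted p = 0.239 with an estimated correlation), and failed with the replicate block (0.163) and without GFP-mCherry replicate 12 (0.0528). Epithelial IL-22 targets were higher in 2 of 22, the acute phase gene Hp by 0.95 and Muc1 by 0.43 (median 0.04, adjusted p = 0.0440, adjusted p = 0.239 with an estimated correlation). That list failed after quantile normalization (0.133), as Muc1 did (0.0657), and without GFP-mCherry replicate 7 (0.0520), 9 (0.101), 12 (0.0541) or 14 (0.0708) or mCherry-Fc replicate 13 (0.118), 14 (0.0644) or 15 (0.0855).

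Immediate early genes did not pass as a list between the ligands (adjusted p = 0.171), with Jun, Ier3 and Phlda1 higher and Egr2, Ier2, Dusp6, Spry4 and Myc lower. MYC (0.331, Myc lower), STAT5 targets (0.985, Cish higher, Id1 lower), the SOCS family (0.295, Cish higher), cytokine receptors (0.171, Il4ra and Ifngr2 higher) and FOXO genes (0.331, Sesn1 higher, Cited2 lower) did not pass either. Oxidative phosphorylation (0.0799) passed as higher without GFP-mCherry replicate 9 (0.0328) or 11 (0.0329) or mCherry-Fc replicate 13 (0.00615) or 14 (0.0149) and after quantile normalization (0.0186), histones (0.158) without GFP-mCherry replicate 11 (0.0216) and ribosomal proteins (0.171) without the same array (0.0453). The amino acid stress (0.957), BCL2 (0.614), G1/S (0.331), glycolysis (0.331), heat shock (0.614), B lineage (0.614), erythroid (0.750), mast cell (0.715, Hdc higher), myeloid (0.546) and T cell lists (0.533) did not pass. Adjusted over the list alone, 16 NF-kB, 9 cholesterol, 13 G2/M, 2 IL-10, 2 epithelial IL-22, 3 STAT3, 13 immediate early, 5 cytokine receptor, 2 FOXO, 2 STAT5, 1 MYC, 1 SOCS and 1 mast cell genes passed.

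Between the ligands 218 genes passed, 144 higher with GFP-mCherry and 74 lower (66.1% higher), 55 differed at least 1.5-fold and 19 at least 2-fold. With the replicate block 100 genes passed, with array weights 478, within low replicate numbers 504 and within high ones 314, with the batch term 469 and with only the 2 groups fitted 460. Within low numbers Fdft1 (adjusted p = 0.113), Tpx2 (0.0643), Muc1 (0.0821), the IL-10 response (0.270), epithelial IL-22 targets (0.847) and STAT3 targets (0.127) lost their calls, and within high ones Sla (0.124) and Tpx2 (0.0628).

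The GFP-mCherry response minus the IL-22 response asked whether the synthetic pair answers as the natural pair does. Socs3 answered less to GFP-mCherry (difference of log2 changes -3.28, SE 0.11, n = 4 and 4 against 6 and 6, limma's adjusted p = 8.96e-18), as did Il2ra (-4.05, SE 0.20, adjusted p = 1.52e-14), Gadd45g (-3.53, SE 0.15) and Il4ra (-2.76, SE 0.11, adjusted p = 1.22e-16). Zfp36 (-2.75), the chemokine receptor gene Cxcr2 (-2.57), Tgm1 (-2.54) and Lbp (-2.49) followed. Stat3 (-1.03, SE 0.08, adjusted p = 8.04e-10), Junb (-0.94), Bcl3 (-0.61) and Socs1 (-0.44) also answered less, while Socs2 did not differ by the test (log2 -0.00, SE 0.16, adjusted p = 0.996) and nor did Egr1, Il10rb, Il22ra1 or Il6st. Nfkbia answered more with GFP-mCherry (3.30, SE 0.27, adjusted p = 1.07e-09), as did Tnfaip3 (2.52), Nfkbie (2.38, SE 0.12), Nfkbiz (1.99), Igsf6 (1.93, larger without IL-22 replicate 5 and 0.77 within high replicate numbers), Gpr84 (1.92), Dusp4 and the lymphotoxin gene Ltb. Myc (0.40, adjusted p = 0.0162) and Pim1 (0.72, adjusted p = 0.0449) answered more, and both failed with the replicate block (0.0708 and 0.124), while Il10rb passed with it (0.0312). Leaving out single arrays ended the calls of Myc without natural untreated replicate 5 (0.0520), of Socs1 without IL-22 replicate 1 (0.0907) or natural untreated replicate 5 (0.0861), and of Igsf6 without IL-22 replicate 1 (0.0817), 2 (0.0616) or 3 (0.0795) or natural untreated replicate 4 (0.0705) or 5 (0.0853). Pim1 failed without IL-22 replicates 1 (0.0632), 2 (0.0573), 3 (0.0800) or 5 (0.0636), natural untreated replicates 4 (0.106) or 5 (0.134), GFP-mCherry replicates 9 (0.0546), 11 (0.0629), 12 (0.0709), 13 (0.0522) or 14 (0.0607), or synthetic untreated replicates 12 (0.0737), 13 (0.0667) or 14 (0.0728), and was -0.16 within low and 1.66 within high replicate numbers.

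STAT3 targets answered less to GFP-mCherry in 17 of 26 (median -0.91, camera's adjusted p = 1.48e-20), with Pim1 and Icam1 answering more, and the IL-10 response in 12 of 17 (median -0.61, adjusted p = 3.37e-16). The SOCS family answered less in 4 of 8, Socs3, Cish, Socs1 and Socs5 (median -0.19, adjusted p = 0.00058), and cytokine receptor and JAK-STAT genes in 8 of 25 (median -0.03, adjusted p = 0.00058), Stat5a at -1.58 and Stat2 at -1.49, with Ifngr2 and Tyk2 answering more. Oxidative phosphorylation genes answered more in 10 of 20 (median 0.26, adjusted p = 3.36e-07), Cox5a by 0.63. These 5 lists also passed with an estimated correlation. STAT5 targets answered less in 8 of 20 (median -0.08, adjusted p = 0.00136, adjusted p = 0.0574 with an estimated correlation), Osm at -2.45, with Pim1, Pim2 and Ccnd2 answering more. NF-kB targets answered more in 9 of 22 (median 0.24, adjusted p = 0.00058, adjusted p = 0.0805 with an estimated correlation), while Rel, Bcl3, Tnip3 and Il6 answered less. The NF-kB list mean per array was 6.94 to 7.02 in untreated synthetic cells and 7.82 to 8.05 with GFP-mCherry. In untreated natural cells it was 7.87 to 8.29, so the larger answer started from a lower level. G1/S genes answered more in 11 of 28 (median 0.23, adjusted p = 8.08e-05, or 0.178 with an estimated correlation), Cdca7 by 0.57. Ribosomal proteins answered more in 6 of 21 (median 0.19, adjusted p = 0.000145, or 0.299 with an estimated correlation), Rplp1 by 0.57. Histones answered more in 4 of 10, H2ac4, H1f5, H2bc3 and H1f1 (median 0.29, adjusted p = 0.000995, or 0.271 with an estimated correlation). Within high replicate numbers STAT5 targets (0.214) failed, and within low ones NF-kB targets (0.180), the SOCS family (0.102) and ribosomal proteins (0.102).

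MYC genes answered more in 7 of 34 (median 0.09, adjusted p = 0.0171, adjusted p = 0.701 with an estimated correlation), Tfrc by 0.76, and failed without IL-22 replicate 5 (0.572), natural untreated replicate 2 (0.0846) or 3 (0.0756) or synthetic untreated replicate 7 (0.0529) and after quantile normalization (0.0721). Cholesterol synthesis answered less in 4 of 20, Hmgcs1, Cyp51, Sc5d and Msmo1, with Tm7sf2 answering more (median -0.20, adjusted p = 0.0231, adjusted p = 0.701 with an estimated correlation). It failed with the replicate block (0.0571), within low replicate numbers (0.841) and without IL-22 replicate 2 (0.0883) or 3 (0.0562), natural untreated replicate 4 (0.134) or 5 (0.0805) or synthetic untreated replicate 13 (0.0780) or 14 (0.0668). Immediate early genes did not pass (0.249), with Dusp4, Dusp6, Spred2, Etv5 and Myc answering more and 6 genes less, nor did FOXO genes (0.658), epithelial IL-22 targets (0.148) or the amino acid stress (0.642), BCL2 (0.850), G2/M (0.642), glycolysis (0.298), heat shock (0.517), B lineage (0.814), T cell (0.615), mast cell (0.615) and myeloid lists (0.642). Erythroid markers (0.0863) passed without natural untreated replicate 5 (0.0435). Their positive differences were in Klf1, which fell with IL-22 and with GFP-mCherry, and in Epor and Tfrc, which fell with IL-22 only. Adjusted over the list alone, 19 STAT3, 13 IL-10, 4 SOCS, 11 STAT5, 12 cytokine receptor, 14 NF-kB, 12 oxidative phosphorylation, 12 G1/S, 7 ribosomal, 5 histone, 7 MYC, 7 cholesterol, 13 immediate early and 3 erythroid genes passed.

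**Figure D3:**
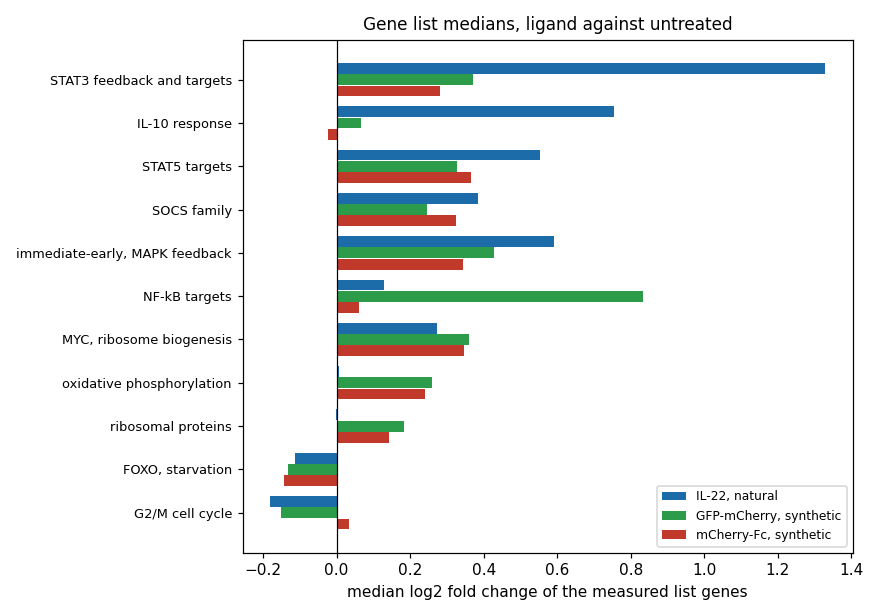
Median log2 change of the measured genes of 11 lists (bars) for each ligand against its untreated cells. STAT3 targets had medians of 1.33 with IL-22, 0.37 with GFP-mCherry and 0.28 with mCherry-Fc, and NF-kB targets 0.13, 0.83 and 0.06.

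The responses differed for 2718 genes, 1840 higher and 878 lower in the synthetic pair (67.7% higher, or 54.7% after quantile normalization), 692 of them by at least 1.5-fold. As alternatives, 4583 genes passed within low replicate numbers, 916 within high ones and 4153 with the batch term. Across genes, which are not independent replicates, the IL-22 and GFP-mCherry changes had a Pearson correlation of 0.247 and a Spearman correlation of 0.126, and the slope over the 2277 genes called with IL-22 was 0.207. The 2 responses shared 473 genes higher in both (153 expected from independent lists) and 276 lower in both (141 expected). Another 240 were opposite, for which no expectation was computed. The expected numbers, here and for the other ligand pairs, treat all genes alike. Among the genes with a mean at or below the median of all, only 126 rose with IL-22, 88 with GFP-mCherry and 80 with mCherry-Fc. Independent lists drawn from the brighter genes would thus share more rises than these numbers. The 749 genes called in the same direction became 907 within low replicate numbers, 273 within high ones and 1135 with the batch term. Of 445 genes at least 1.5-fold higher with IL-22, 206 were also higher and 20 lower with GFP-mCherry, with median log2 changes of 0.88 and 0.21. For mCherry-Fc the correlations with IL-22 were 0.227 and 0.109, with 482 genes higher in both (150 expected), 177 lower in both (156 expected) and 198 opposite, and 203 of the 445 were also higher.

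**Figure D4:**
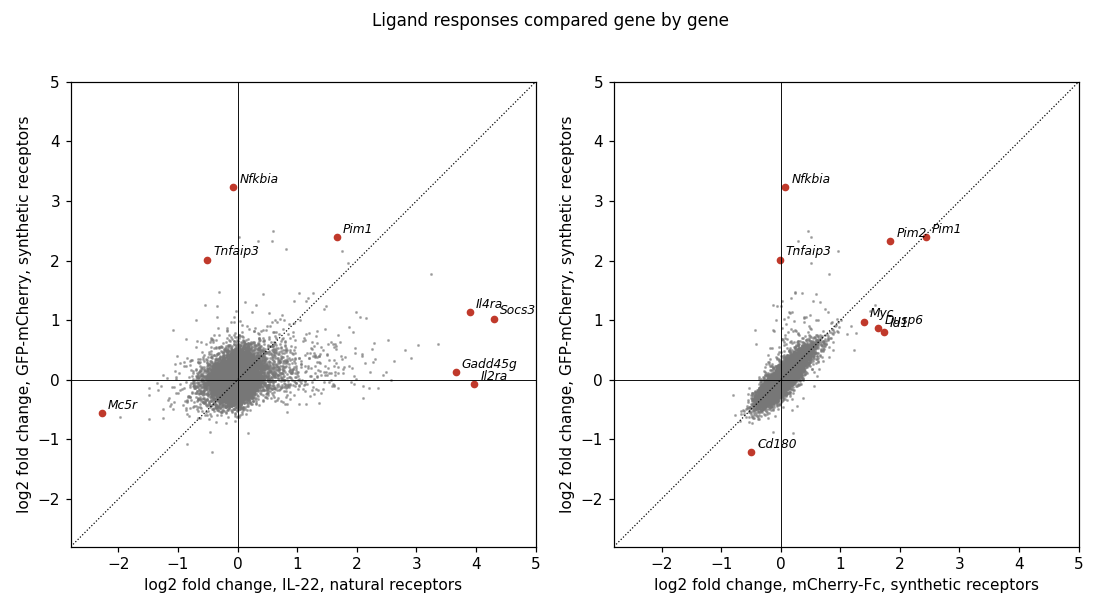
Log2 change per gene (points) with GFP-mCherry on the vertical axes against the change with IL-22 (left) and with mCherry-Fc (right) on the horizontal axes, with named genes in red and equal change as a dotted line. The Pearson correlation across genes was 0.247 with the IL-22 changes and 0.835 with the mCherry-Fc changes, which share their untreated arrays with GFP-mCherry.

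The overlap of the mCherry-Fc and GFP-mCherry responses covered most calls of both. Of 124 genes at least 1.5-fold higher with mCherry-Fc, 120 were also higher with GFP-mCherry, with median log2 changes of 0.70 and 0.65, and among them were Pim1, Pim2, Dusp4 and Etv5. In all, 2189 genes were higher in both (397 expected from independent lists), 1398 lower in both (304 expected) and 2 opposite. The Pearson correlation across genes was 0.835, the Spearman correlation 0.842 and the slope over genes called with mCherry-Fc 0.916. Both comparisons use the same untreated arrays and no control protein. Simulated unchanged groups against those arrays gave a mean correlation of 0.494 (highest 0.841 of 100 draws), a mean covariance of 0.00351 against 0.0327 observed, and 0 genes called in both by limma, and the covariance difference was 0.0292. With the untreated arrays split 3 and 3 between the comparisons the mean correlation was 0.661 (0.333 to 0.753 over 20 splits), the mean covariance 0.0283 and 1460 genes on average were called in both (1147 to 1955). The 3587 genes called in the same direction became 3468 within low replicate numbers, 2511 within high ones and 5168 with the batch term.

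Untreated synthetic against untreated natural receptor cells asked how far the lines differed before any ligand. No replicate number occurs in both lines, so line, clone and day of work cannot be told apart. Beside Il22ra1, the largest differences were lower levels in synthetic cells. Itgam, the CD11b integrin of myeloid cells, was 26.8-fold lower (log2 -4.75, SE 0.55, n = 6 against 4, limma's adjusted p = 4.65e-07), at 10.34 ± 1.76 in natural and 5.59 ± 0.38 in synthetic cells. The chemokine gene Ccl3 was 25.2-fold lower (log2 -4.66, SE 0.18, adjusted p = 6.04e-17), Lcn2, which captures bacterial iron carriers, 14.4-fold (log2 -3.85, SE 0.58, adjusted p = 2.08e-05) and Tnip3 14.0-fold (log2 -3.81, SE 0.13, adjusted p = 3.38e-18). Cd74, the invariant chain of MHC class II (log2 -3.65), Milr1 (-3.46) and Tspan8 (-3.45) were also lower. Higher in synthetic cells were Wfikkn2 (2.93), Wfdc15a (2.84), Tek, an angiopoietin receptor (2.81, SE 0.08, adjusted p = 4.83e-20), Arhgap15 (2.19), Lrriq3 (1.96), Klhl6 (1.91), Serpini1 (1.90) and Ptprcap. Pim1 (-1.18), Cish (-0.75) and Myc (-0.28, adjusted p = 0.0156) were lower, and Myc failed without natural untreated replicate 4 (0.0770) or 5 (0.139). Socs3 (-0.10), Stat3 (0.11), Socs1, Socs2, Junb, Egr1 and Il6st did not pass, nor did Bcl3 (-0.26, adjusted p = 0.0601), which passed without synthetic untreated replicate 7 (0.0288) or 9 (0.0404). Of 54 called named genes, all 54 had every synthetic array on the called side of the natural mean, and 52 had no overlap.

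NF-kB targets were lower in synthetic cells in 17 of 22 (median -0.64, camera's adjusted p = 1.32e-24), Nfkbia at -2.52. Immediate early and MAPK feedback genes were lower in 15 of 30 with Btg2 and Klf6 higher (median -0.24, adjusted p = 1.28e-11), Etv5 at -1.81 and Dusp6 at -1.50. Amino acid and endoplasmic reticulum stress genes were lower in 14 of 28 with Xbp1 higher (median -0.24, adjusted p = 6.92e-09), the cystine transporter gene Slc7a11 at -2.05 and the asparagine synthetase gene Asns at -0.63. STAT5 targets were lower in 9 of 20 with Xbp1 higher (median -0.22, adjusted p = 3.98e-07), Pim2 at -3.33. The IL-10 response was lower in 6 of 17 (median -0.13, adjusted p = 5.19e-06), and epithelial IL-22 targets in 7 of 22 (median -0.05, adjusted p = 6.03e-05), Hp at -1.61 and Lbp at -1.44. These 6 lists also passed with an estimated correlation. MYC genes were lower in 21 of 34 with Fbl and Tfrc higher (median -0.30, adjusted p = 1.28e-11, adjusted p = 0.135 with an estimated correlation), Srm at -0.83. Cholesterol synthesis genes were higher in 11 of 20 (median 0.36, adjusted p = 4.24e-09, adjusted p = 0.170 with an estimated correlation), Dhcr7 by 0.71 and Nsdhl by 0.55. STAT3 targets were lower in 9 of 26 (median -0.23, adjusted p = 5.19e-06, adjusted p = 0.0983 with an estimated correlation), and myeloid markers in 8 of 17 with Prtn3 higher (median -0.40, adjusted p = 5.19e-06, adjusted p = 0.135 with an estimated correlation). Oxidative phosphorylation genes were higher in 8 of 20 (median 0.10, camera's adjusted p = 0.0165, adjusted p = 0.314 with an estimated correlation). In that list Cycs was lower by the probe set used (log2 -0.40) and by another (-0.41), but a further Cycs probe set at -0.07 did not pass. Cytokine receptors passed as lower (median -0.06, adjusted p = 0.0165, adjusted p = 0.0943 with an estimated correlation), with Il22ra1, Il10rb, Ifngr2, Il22ra2 and Il4ra lower and Ifngr1, Stat2, Stat5a and Stat5b higher, and failed without natural untreated replicate 5 (0.1). Erythroid markers were higher in 4 of 10, Klf1, Tal1, Tfrc and Gata1 (median 0.08, adjusted p = 0.0189, adjusted p = 0.132 with an estimated correlation), and failed without synthetic untreated replicate 7 (0.0508).

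Lists that did not pass between the untreated lines were the SOCS family (adjusted p = 0.740, Socs5 higher, Cish lower), G1/S (0.662, 8 higher, and Ccnd2, Ccne1, Cdc25a and Cdca7 lower), G2/M (0.569), FOXO (0.449), ribosomal proteins (0.628), the BCL2 family (0.509), glycolysis and hypoxia (0.406), histones (0.612), and B lineage (0.612), mast cell (0.662) and T cell markers (0.569). Heat shock genes (0.106, Hspa8 and Dnaja1 lower) passed as lower without natural untreated replicate 4 (0.0485). Among these the BCL2, G1/S, G2/M, B lineage, mast cell and SOCS lists had a median, mean and test that differed in sign. Adjusted over the list alone, 20 NF-kB, 19 immediate early, 17 amino acid stress, 12 STAT5, 7 IL-10, 8 epithelial IL-22, 24 MYC, 15 cholesterol, 11 STAT3, 11 myeloid, 10 oxidative phosphorylation, 12 cytokine receptor, 4 erythroid, 14 G1/S, 2 SOCS and 2 heat shock genes passed.

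Between the untreated lines 3034 genes passed, 1715 higher and 1319 lower in synthetic cells (56.5% higher), 469 of them by at least 1.5-fold and 159 by at least 2-fold, and 2347 passed within low replicate numbers, 5750 within high ones and 1722 with only the 2 groups fitted, where Atp5c1, Uqcrc2 and Myc lost their calls. Within low numbers cholesterol synthesis (adjusted p = 0.157), STAT3 targets (0.128), myeloid markers (0.157), the IL-10 response (0.0565), oxidative phosphorylation (0.193), cytokine receptors (0.387) and erythroid markers (0.0565, and 0.148 within high numbers) failed. So did Cish (0.1002), Tfrc (0.0688), Atp5c1 (0.0503), Uqcrc2 (0.199) and Myc (0.847), and Pim1 was at -0.36 against -2.00 within high numbers. FOXO genes (0.0428), G2/M (7.96e-05), glycolysis (0.000185) and ribosomal proteins (0.0169) passed within low numbers.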

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

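Of the tests below, 5 were chosen only after the result was seen. They are the joining of the chains for the NF-kB genes, the starting level, the receptor level and the batch within low numbers for the STAT3 genes, and repression for the olfactory receptor genes. The bound used to read the background test was also tightened after its first run, which left that explanation open where it had been excluded. The splits by replicate number range were chosen after seeing the data.

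The first pattern is that NF-kB targets stood higher with GFP-mCherry than with mCherry-Fc. Each group holds 3 low and 3 high replicate numbers, so a batch between them that acts on all groups alike cannot make the difference, and the list median was 0.817 within low and 0.724 within high numbers. Joining of IL-10R2 with IL-22Rα1 as such is a candidate explanation, since the 15 NF-kB genes that rose with GFP-mCherry had a median log2 change of 0.478 with IL-22 and 10 of them rose, though the median over all 22 list genes was 0.13. It does not account for all of them, since Tnfaip3 (-0.51) and Tnip1 (-0.44) fell with IL-22, and Nfkbie (0.02) and Nfkbia (-0.07) did not pass, while 4 of the 15 stood in untreated natural cells at or above their level in treated synthetic ones. A Toll-like receptor ligand carried with the GFP-mCherry protein was not tested and stays open, as do the differences of ligand and line.

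The second pattern is that STAT3 targets answered less to GFP-mCherry than to IL-22. A batch between replicate number ranges is argued against, since within low numbers, with 3 IL-22 arrays, the list median was -1.08. For the list mean per array, 2 standard errors of this difference were 0.0969, with the spread pooled over all groups and ranges. The -0.558 within high numbers rests on IL-22 replicate 5 alone, takes its spread from other groups and excludes nothing. A higher starting level of these genes in synthetic cells is argued against too, since their median was lower there, at -0.228. A lower level of the receptor chains cannot be told apart from other differences between the lines, since Il10rb (-1.89) and 1 Il22ra1 probe set (-6.00) were lower and the other Il22ra1 probe set was not, and where the probes lie on the constructs is not given. Receptor design, ligand and cell line changed together, so these arrays do not separate them.

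The third pattern is that the 1027 olfactory receptor genes measured stood slightly lower with either synthetic ligand. Each synthetic group holds 3 low and 3 high numbers, and the medians were -0.077 with GFP-mCherry, -0.092 with mCherry-Fc and -0.022 with IL-22, with 112, 148 and 5 genes called lower and 1, 6 and 1 higher, and after quantile normalization the synthetic medians were -0.025 and -0.030 with 44 and 43 genes lower. It is not particular to these genes. Among all dimmer genes 1240 were called lower and 88 higher with GFP-mCherry, 1685 and 80 with mCherry-Fc, and 95 and 126 with IL-22. Lower background on the treated arrays stays open. The 4023 dim probe sets without a gene had medians of -0.0137 with GFP-mCherry and 0.00985 with mCherry-Fc, the latter not a fall. But 2 standard errors, taken from the median per array, were 0.0632 and take in the -0.03 that lower background would need. Repression by the receptors (median -0.0767) cannot be told from lower background. No genes known not to respond set the scale, and olfactory array medians, 3.82 to 4.00, were dim.

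Chance as the source of each count was tested by splitting the same arrays in other ways. It can be excluded at 100 drawn splits for GFP-mCherry against untreated (5183 genes, highest other 2626), for mCherry-Fc against untreated (5371, highest other 3236), for GFP-mCherry against mCherry-Fc (218, highest other 1) and for the difference of responses (2718, highest other 1109). A split by number range gave 3636 genes for mCherry-Fc and untreated arrays and 54 for GFP-mCherry and untreated arrays. For the untreated lines it can be excluded too (3034), with 2 of 100 splits as large, the real one included. The highest other, 3147, set natural 2 to 5 with synthetic 7 and 11 against synthetic 9, 12, 13 and 14. For IL-22 against untreated, 2 of all 35 splits, the real one included, gave as many genes, so chance is not excluded by this count (2277). The highest other, 2332, set IL-22 replicates 1, 2 and 3 with untreated 3 against IL-22 5 with untreated 2, 4 and 5. That split keeps 3 of the 4 IL-22 arrays together, so it holds part of the IL-22 difference, and it partly follows the number ranges. With these as a batch term 3021 genes passed, with 3212 within low and 759 within high numbers. Among the 30 splits that exchange labels only within a range, a test added after the 35 were seen, only the real one gave as many as 3021 (highest other 634).

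Single arrays lay far from the rest of their group for 35 of 535 gene and group pairs, where about 27 would by chance at 1 in 20. Of the 35, 17 came from IL-22 replicate 5, whose array weight was 0.295. The gap to the nearest array as a share of the group's range was 0.852 for Il4ra (12.34 against a median of 12.82 in the others), 0.904 for Gadd45g, 0.873 for Osm, 0.904 for Ccng2 (8.97 against 6.56), 0.951 for Sh2d3c, 0.931 for Sbno2, and 0.850 for Egr2 (8.14 against 9.35). It was 0.861 for Parp14, 0.922 for Irf9, 0.879 for Nop2, 0.908 for Rrp12 and 0.859 for Stat3. It was 0.880 for Il22ra1, 0.926 for Nfkbiz, 0.882 for Igsf6 (10.60 against 7.77), 0.855 for Ltb and 0.851 for Sc5d. On that array the 445 genes raised at least 1.5-fold by IL-22 averaged 8.85, against 9.10 to 9.18 on the other IL-22 arrays and 7.95 to 8.08 on untreated ones. The 173 lowered genes averaged 8.29, against 7.83 to 7.92 and 8.71 to 8.82. Without IL-22 replicate 5 the count of genes was 3112.

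Other single arrays were natural untreated replicate 5 for Il4ra (0.959), Sesn1 (0.848) and Cebpd (0.860), replicate 2 for Xbp1 (0.851) and replicate 4 for Uqcrc2 (0.896). Among GFP-mCherry arrays replicate 12 stood apart for Nfkbiz (0.658), Gadd45a (0.651), Tnip3 (0.785), Il22ra1 (0.705) and Hhex (0.760), and replicate 11 for Gpr84 (0.681), Ccnd2 (0.644) and Nop2 (0.628). Synthetic untreated replicate 14 stood apart for Dusp6 (0.754), and mCherry-Fc replicate 13 for Tsc22d3 (0.717), 9 for Il22ra1 (0.626) and 10 for Slc2a6 (0.632) and Icam1 (0.790).

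The responses to GFP-mCherry and IL-22 differed, by limma's interaction test, for 2718 genes. The largest differences were 3.30 for Nfkbia, 2.52 for Tnfaip3, 2.38 for Nfkbie, 1.99 for Nfkbiz, 1.93 for Igsf6, 1.92 for Gpr84, 1.8026 for Dusp4 and 1.7952 for Ltb, with GFP-mCherry higher. With IL-22 higher they were -4.05 for Il2ra, -3.53 for Gadd45g, -3.28 for Socs3, -2.76 for Il4ra, -2.75 for Zfp36, -2.57 for Cxcr2, -2.54 for Tgm1 and -2.49 for Lbp.

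Of the 12146 probe sets paired with no gene, which no comparison uses, 78 were higher than untreated with IL-22, 441 with GFP-mCherry and 465 with mCherry-Fc, while 30, 887 and 1016 were lower. At least 2-fold rises numbered 20, 9 and 12, and the largest with IL-22 was probe set 10398039 (log2 3.43).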

How the results depend on the processing

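The settings by replicate number range, low or high numbers only and the batch term, were chosen after seeing the data, and the rest were planned. Where a count or call changed, the cause was not tested, except that a stricter fold minimum lowers a count by construction. Fewer arrays lowered some counts and raised others, such as 3112 genes for IL-22 without IL-22 replicate 5 against 2277.

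Of 332 gene results and 156 list results, 323 and 146 stayed on their side of the threshold after quantile normalization, and 326 and 154 after median centring. With the mean of probe sets 327 and 156 stayed, with array weights and with a trended and robust prior 330 and 156 each, and with only the groups compared 320 and 153. With an estimated correlation 114 of 156 list results stayed and 42 lost their call, and with fry 134 stayed. Without the lowest genes by mean, 143 of 156 list results stayed under the lenient filter and 132 of 150 under the stricter one. None of these settings reversed a called result.

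Quantile normalization gave 3146 genes for mCherry-Fc. Array weights gave 478 between the ligands. With only the groups compared, 1222 genes passed for IL-22, 460 between the synthetic ligands and 1722 between the untreated lines. With a change of at least 1.5-fold the counts were 618 for IL-22, 224 for GFP-mCherry, 133 for mCherry-Fc, 55 between the ligands, 692 for the difference of responses and 469 between the untreated lines.

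With the replicate block 2184 genes passed for IL-22, 6562 for GFP-mCherry, 3991 for mCherry-Fc, 100 between the ligands and 3071 for the difference of responses. Of 270 gene results 252 stayed, and of 130 list results 124. The block ended the calls of Dnaja1, Tfrc and Epor with IL-22, and of Pmvk, Pfkfb3, Junb and histones with mCherry-Fc. It also ended those of 9 genes and the IL-10 and STAT3 lists between the ligands, and of Pim1, Myc and cholesterol synthesis in the difference of responses. It made calls of Il10rb in that difference and of epithelial IL-22 targets with IL-22 and with mCherry-Fc, and changed no other call. For GFP-mCherry against untreated the numbers do not pair the arrays, with 2 of 6 correlating best with their own number. The random replicate block (correlation 0.255) gave 2898, 6977, 6532, 304 and 3967 genes in the same order. The untreated lines share no number, so no paired analysis was possible.

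The batch term gave 469 genes between the ligands, 4153 for the difference of responses and 1135 for genes called alike with IL-22 and GFP-mCherry. Low numbers alone gave 504 between the ligands and 4583 for the difference of responses, and changed the sign of Pim1 in that difference (-0.16). They also called Socs2 lower between the untreated lines (-0.40), which was not called with all arrays (0.004). High numbers alone gave 759 for IL-22, 916 for the difference of responses, 5750 between the untreated lines and 273 called alike. There, 303 of 332 gene results stayed, and 311 within low numbers.

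Leaving out each array in turn gave 1720 to 3112 genes for IL-22, 4255 to 5955 for GFP-mCherry, and 3834 to 6460 for mCherry-Fc. It gave 166 to 200 between the ligands, 2136 to 3438 for the difference of responses and 2058 to 3363 between the untreated lines. Genes called alike numbered 596 to 952 with IL-22 and GFP-mCherry and 2791 to 4422 with both synthetic ligands. Of 4052 gene results so obtained 4003 stayed, and of 1924 list results 1856. How far signal over background limits the calls was not tested.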

Other observations

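The gene families below were chosen, among those looked at, after the data were seen, and no enrichment or cause was tested. Over all 19938 genes 2839 rose with GFP-mCherry, 2788 with mCherry-Fc and 1075 with IL-22.

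Of 77 Mrp genes, of the mitochondrial ribosome, 56 rose with GFP-mCherry (median log2 0.26) and 55 with mCherry-Fc (0.24), against 5 with IL-22 (0.03). With the synthetic ligands 38 and 31 genes rose after quantile normalization, when 2 fell with GFP-mCherry, and 63 and 65 after median centring. Of 39 Psm genes, of the proteasome, 23 rose with GFP-mCherry (median 0.20) and 21 with mCherry-Fc (0.17), or 20 and 14 after quantile normalization, when 1 fell with each, and 26 and 26 after centring. With IL-22, 3 of the 39 rose. Of 18 Nop and Utp genes, which serve the nucleolus in making ribosomes, 13 rose with GFP-mCherry, 14 with mCherry-Fc and 6 with IL-22 (medians 0.31, 0.34 and 0.20), with 11, 11 and 8 after quantile normalization and 14, 17 and 6 after centring. RNA polymerase subunit genes, 27 in all, rose in 13 with each synthetic ligand (medians 0.18 and 0.16), while 1 and 2 fell, and 2 rose with IL-22 (-0.01). After quantile normalization 8 rose and 3 fell with GFP-mCherry (0.09) and 10 rose and 2 fell with mCherry-Fc (0.07), and after centring 18 rose and 1 fell with each (0.26 and 0.25).

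With IL-22, all 3 Trim30 genes measured rose (median 1.44, 1.38 after quantile normalization and 1.47 after centring), and 4 of 11 Oas genes rose while 1 fell as deposited and none after either scaling. Neither synthetic ligand raised a Trim30 or Oas gene by limma's test under any of the 3 scalings.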
